A study of Homo sapiens with 8 samples.

How the data were processed

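Chromatin accessibility was measured by ATAC-seq in LNCaP cells, an established androgen-sensitive human prostate cancer line, in 8 libraries, with 1 library per group. In ATAC-seq the Tn5 transposase inserts sequencing adapters into open chromatin, and regions with many insertions are called as peaks. Per the labels, the cells were kept in charcoal-treated medium, which is depleted of steroids, before they received vehicle (methanol), 10 nM dihydrotestosterone (DHT), 10 µM bicalutamide or DHT with bicalutamide, for 5 h or 5 days. Groups were taken from the sample titles, which give the agent and the time. The treatment text that accompanies the labels also names a further antagonist and another collection time, and neither was used for grouping.

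The deposited files were peak lists, 1 per library, which hold other values than reads or signal, namely the chromosome, the start and the end of each peak. They gave no score, height, fold enrichment or p-value, and no read numbers. Per the submitters' processing notes, BWA 0.7.17-r1188, Bowtie2, Picard 2.18.16, MACS2 2.1.2 and HOMER 4.9.1 were used, without a statement of which step each tool served. Whether insertion positions were shifted for the Tn5 offset, which threshold was used for peaks and which minimum length applied are not given in the sources used here. The same notes name the builds hg19 and GRCh38 with no role for either. The positions were checked against the ends of protein-coding genes of GRCh38: of the peaks of at least 73 bp, 11.3% to 38.2% per list lay within 500 bp of a gene end, against 1.55% to 1.90% after every position was moved by 1 Mb. Coordinates are therefore given in GRCh38, as the lists give them. Whether the starts count from 0 or from 1 is not recorded, so a start may be off by 1 bp.

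The peak lists differed in how they ended at the short side. The shortest peak was 73 bp in the vehicle 5 h list and 66 bp in the DHT with bicalutamide 5 day list, but 20 or 21 bp in the other 6 lists, where 57.5% to 78.7% of the peaks were under 40 bp. A threshold of 73 bp, the longest of the 8 shortest peaks, was therefore added after the lists were seen, and peaks of at least 73 bp are called wide peaks here. In comparisons of wide peaks, a wide peak of the first list was set against all peaks of the second list, so that a narrow call in the second list still counted as shared, and lost wide peaks were wide peaks of the second list set against all peaks of the first.

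Peaks of different lists were taken as shared when they overlapped by at least 1 bp (bedtools 2.31.1). A peak of the first list of a comparison without an overlapping peak in the second is called gained, and a peak of the second list without one in the first is called lost. These words describe calls and not tested changes. The 6 comparisons between agents, the time comparison within each agent, the gene lists and the rule for named genes were fixed before the data were examined. Because the peak lists carry no score, peak width replaced the score wherever the rule for named genes or the matching of peaks would have used it. The rule names, for each comparison, the 5 widest gained and the 5 widest lost peaks by nearest gene, up to 10 androgen-induced genes with the widest gained or lost peaks, and up to 4 such genes of each other list. The report prints a part of these, and sites at some genes named by the rule are not reported here.

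Each peak centre was assigned to the nearest span of 20037 protein-coding genes of GRCh38, within 100 kb. The gene table used here holds spans without strand, exons or untranslated regions, so the nearest span replaced the nearest transcription start site that had been planned, and a site inside a span is not placed in an exon or intron. The 11 gene lists held 163 genes, all of which matched the table. They were androgen-induced and androgen-repressed genes, luminal, basal and neuroendocrine prostate markers, stromal and blood cell markers, cell cycle genes, immediate early genes, lipid synthesis genes and housekeeping genes. For each list the sites gained and lost were counted, and their percentile was taken among 10000 random gene lists of the same size, matched in 20 bins on the mean number of sites per gene over all libraries. Members of near-identical families (the UGT2B genes, the kallikreins) can share reads, and whether the authors removed such reads is not given in the sources used here.

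To ask whether sites gained with DHT were also called with the antagonist, the percent found in another list was set beside the same percent over DHT peaks shared with vehicle, drawn 1000 times at the same widths. The overlap of DHT-gained and bicalutamide-gained sites, which share a vehicle library, was set beside the overlap of independent lists and beside 100 simulated pairs of unchanged lists. For wide peaks this overlap used regions merged from the wide peaks of every list, so narrow vehicle calls did not count as shared there. With no replicates, no test between conditions was run and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and the sequencing depth behind each list is unknown. The overlap code was tested on simulated copies of the DHT 5 h list of 141353 peaks and recovered shares of 19.9%, 49.9% and 80.2% as put in. The list percentile was tested on 200 random gene lists among 20037 genes, with simulated numbers of gained and lost sites per gene. It had a median of 50.7, placed 6.0% of the random lists above the 95th percentile and placed a planted list at 100. The test did not use the observed peaks, so it does not show how the percentile behaves on them.

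Reciprocal overlap of at least 50% of both peaks, a gene distance of 20 kb and several settings added later (peak centres within 250 bp, wide peaks, an equal number of the 14534 widest peaks per list, the vehicle library of the other time) were run as alternatives. Searches for androgen response elements and other sequence motifs had been planned and were not run, since no genome sequence was used here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.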

Results

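ATAC-seq peak lists were compared for LNCaP cells given vehicle, the androgen DHT (10 nM), the antiandrogen bicalutamide (10 µM) or both agents, each for 5 h and for 5 days, with 1 library in each of the 8 groups. The lists held 116357 (vehicle), 141353 (DHT), 126296 (bicalutamide) and 106846 (DHT with bicalutamide) peaks at 5 h. At 5 days they held 87924, 139178, 116008 and 66136 peaks in the same order. Merged over all lists, the peaks formed 247239 regions, of which 35.0% were called in 1 list and 11.3% in all 8. There are no replicates, so no difference was tested against replicate spread, and read depth is unknown.

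Peak widths differed between the lists in a way that bears on every comparison. The median width was 128 bp in the vehicle 5 h list and 109 bp in the DHT with bicalutamide 5 day list, but 21 to 23 bp in the other 6 lists. Wide peaks, of at least 73 bp, made up all 116357 peaks of vehicle at 5 h and 14534 (16.5%) at 5 days. They numbered 48323 (34.2%) and 47503 (34.1%) with DHT, 41164 (32.6%) and 32047 (27.6%) with bicalutamide, and 27683 (25.9%) and 45300 (68.5%) with both agents, at 5 h and 5 days. In vehicle at 5 h the wide peaks include the calls near its shortest width, with 24.1% of its peaks in the 10 bp bin from 70 bp. Wide peaks of that list are therefore not the same kind of call as those of lists with a shortest peak of 20 or 21 bp. Peaks under 40 bp lay within 500 bp of a gene end in 2.21% to 3.32% of cases per list, against 1.08% to 1.16% after a shift of 1 Mb, so the named sites are wide peaks unless a shorter width is given.

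**Figure D1:**
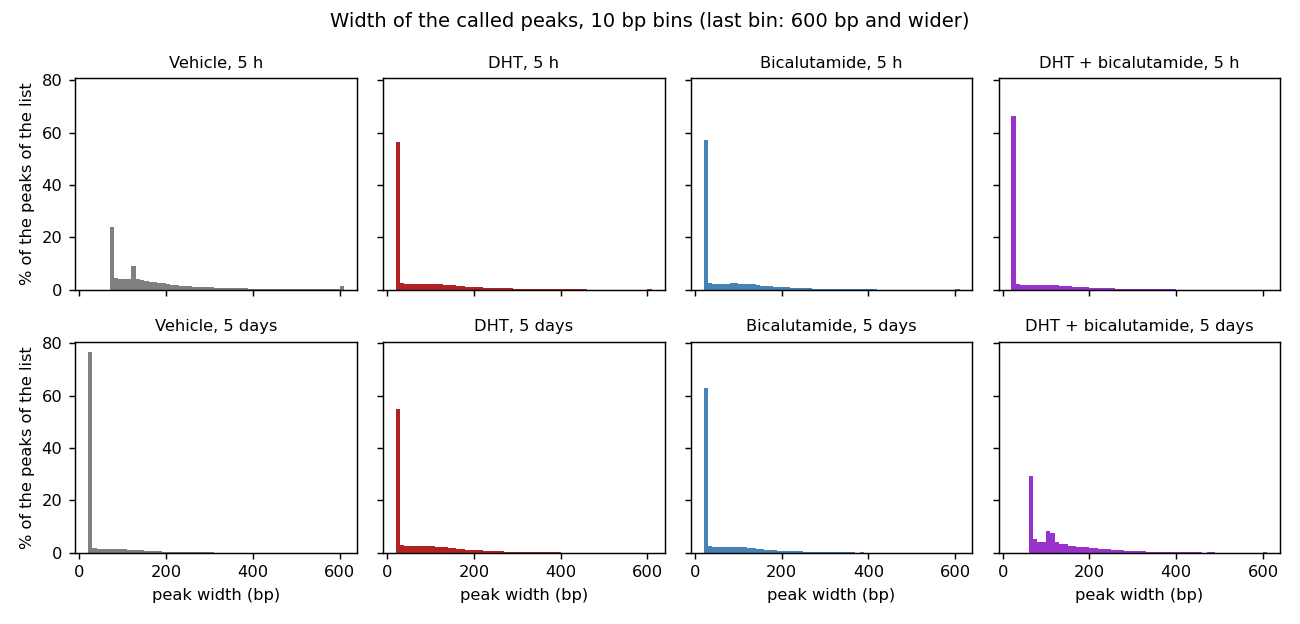
Peak width in bp (x axis, 10 bp bins, the last bin holding peaks of 600 bp and wider) against the percent of the list's peaks (y axis), in 1 panel for each of the 8 libraries. The vehicle 5 h and DHT with bicalutamide 5 day lists hold no peak under 40 bp, whereas the other 6 lists hold 57.5% to 78.7% of their peaks there.

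The comparison of DHT with vehicle at 5 h asked which sites were called early after androgen exposure. Near KLK3, which encodes prostate-specific antigen, a 391 bp DHT peak without a vehicle peak had its centre 590 bp beyond the gene span (chromosome 19, 50861159 to 50861550). It was also called with DHT at 5 days and with both agents at 5 days. Gained DHT peaks of 218 bp lay inside FKBP5 (chromosome 6, 35722544 to 35722762), which encodes a cochaperone of steroid receptors, and of 203 bp inside STEAP4 (chromosome 7, 88303536 to 88303739), a metalloreductase gene. Others lay near the elongation factor gene ELL2 (216 bp wide, chromosome 5, 95857317 to 95857533), the ion channel gene TRPM8 (260 bp wide, chromosome 2, 234020441 to 234020701) and PMEPA1 (245 bp wide, chromosome 20, 57773359 to 57773604). Those of FKBP5, ELL2 and PMEPA1 were called in all 4 lists that contain DHT and in no vehicle or bicalutamide list.

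Wide DHT peaks were gained at 31 of the 144 sites of androgen-induced genes (21.5%, 15.1 to 29.1), spread over 18 of the 30 genes, against 13.0% over all genes. This number lay at the 99.0 percentile of random gene lists, whose median was 18 sites. More sites of this list were lost than gained, with a balance of -55 (percentile 99.6), where lost sites are wide vehicle peaks. Over all peaks, narrow ones included, the list gained 128 of 306 sites and lay at the 33.2 percentile, so the standing of this list rests on the wide peaks. Androgen-repressed genes gained 8 of 36 sites (percentile 88.8), among them a 190 bp site assigned to the chemokine receptor gene ACKR3. Gained sites numbered 5 of 50 for luminal markers (percentile 26.8), among them KRT8 and CDH1, 6 of 23 for basal markers (83.5), 2 of 19 for neuroendocrine markers (54.4), 7 of 65 for lipid synthesis genes (52.8) and 3 of 43 for immediate early genes (10.8). Markers of other cell types gained 2 of 16 sites for stroma (62.7) and 2 of 9 for blood (77.6), and housekeeping genes 3 of 38 (28.7). None of the 31 wide sites at cell cycle genes was gained, which allows a share of up to 11.2% (percentile 0.65). Over all peaks blood markers gained 18 of 31 sites (98.3), luminal markers 27 of 96 (0.39), immediate early genes 21 of 81 (0.275) and cell cycle genes 8 of 51 (0.16).

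The widest gained DHT peak at 5 h (561 bp, chromosome 1, 157284175 to 157284736) had no protein-coding gene within 100 kb and was called in the 4 DHT-containing lists. The next were near COX10 (534 bp wide), a cytochrome oxidase assembly gene whose site was called in every list except vehicle, and inside GNAQ (503 bp, chromosome 9, 78003725 to 78004228) and ENPP4 (chromosome 6, 46137128 to 46137628). Lost sites included a 420 bp vehicle peak inside TMPRSS2, an androgen-regulated protease gene (chromosome 21, 41506885 to 41507305, also called with bicalutamide), a 210 bp vehicle peak inside KLK3 and a 303 bp vehicle peak inside CENPN, a centromere protein gene. DDX1, an RNA helicase gene, lost a site of 817 bp that was called in all 7 other lists. Wide gained DHT sites lay within 1 kb of a gene end in 6.92% of cases (6.33 to 7.55), against 22.0% for shared peaks of the same widths, and 48.0% lay inside a gene span farther from its ends. Wide sites gained with bicalutamide at 5 h also lay there less often than shared ones (12.3% against 20.4%), so this is not particular to DHT.

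Among all DHT peaks at 5 h, 65189 of 141353 (46.1%, 45.9 to 46.4) had no vehicle peak, and 42218 of the 116357 vehicle peaks (36.3%, 36.0 to 36.6) had no DHT peak. Among wide DHT peaks the gained share was 6822 of 48323 (14.1%, 13.8 to 14.4) and the other gained peaks were under 73 bp, a width at which this vehicle list holds no peak.

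**Figure D2:**
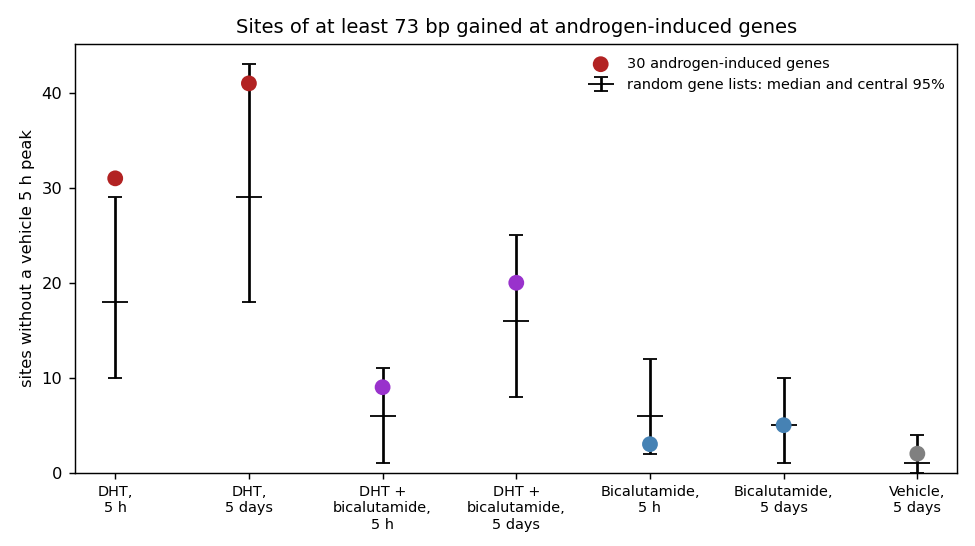
Number of wide sites without a vehicle 5 h peak (y axis) at the 30 androgen-induced genes (dots) in the 7 other libraries (x axis), with the median and the central 95% of 10000 random gene lists in black. DHT at 5 h had 31 such sites against a random median of 18, DHT at 5 days 41 against 29, both agents 9 and 20 at 5 h and 5 days, and bicalutamide 3 and 5.

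At 5 days the DHT list was compared with the vehicle list of 5 days. An ACSL3 site of 322 bp (chromosome 2, 222786222 to 222786544), assigned to this fatty acid activating enzyme gene with its centre 74653 bp away, was called in both DHT lists and in no other. FKBP5 had a 321 bp gained site inside its span (chromosome 6, 35590647 to 35590968), also called with both agents at 5 days. A 292 bp site near PTGER4, a prostaglandin receptor gene (chromosome 5, 40649880 to 40650172), was called in both DHT lists and with both agents at 5 days. DDC, the dopa decarboxylase gene on the androgen-repressed list, had a 291 bp site (chromosome 7, 50502432 to 50502723) called only with DHT at 5 days. The widest gained peak lay inside DOCK5 (770.0 bp, chromosome 8, 25312350 to 25313120) and was absent from both vehicle lists, whereas those at ELMO3, TMEM87B, DHRS2 and CYB561D2 (621 to 663 bp) were called in vehicle at 5 h. Lost sites included a 383 bp peak inside NR6A1, an orphan nuclear receptor gene (chromosome 9, 124769514 to 124769897), called in both vehicle lists alone, and a 171 bp peak assigned to TMPRSS2.

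Over all peaks, androgen-induced genes gained 198 of 305 sites at 5 days (64.9%, 59.3 to 70.3; percentile 98.4) and lost 38 of 149. Over wide peaks they gained 92 of 129 (71.3%, 62.7 to 78.9), against 60.7% over all genes, at the 82.4 percentile. Set against the vehicle list of 5 h instead, the same wide DHT peaks gained 41 of 129 sites (31.8%, 23.9 to 40.6; percentile 95.8). Cell cycle genes gained 13 of 35 wide sites (percentile 4.2) and 28 of 57 over all peaks (43.6), and androgen-repressed genes 25 of 33 (68.3) and 58 of 134 (14.1). The DHT list at 5 days had 71063 of 139178 peaks without a vehicle peak (51.1%, 50.8 to 51.3) and the vehicle list 19408 of 87924 without a DHT peak (22.1%, 21.8 to 22.3). Among wide DHT peaks 29715 of 47503 were gained (62.6%, 62.1 to 63.0), and 64.4% of these were called in vehicle at 5 h.

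Bicalutamide at 5 h was compared with vehicle to see which sites an antagonist alone gains or loses. Its widest gained peaks with a gene within 100 kb lay inside RIMS3 (334 bp), GOLGA4 (289 bp) and EGFL7 (283 bp) and near KIF3B (282 bp), and all 4 sites were also called with DHT at 5 h. Androgen-induced genes gained 3 of 97 wide sites (3.09%, 0.642 to 8.77; percentile 9.2), at MAF (137 bp), ABCC4 (93 bp) and PMEPA1 (79 bp). A 282 bp vehicle site assigned to KLK2, a kallikrein gene beside KLK3 (chromosome 19, 50869450 to 50869732), was called in both DHT lists and in neither list of bicalutamide alone. With both agents it was called at 5 days (83 bp) and not at 5 h. Sites of 211 bp inside TMPRSS2 (chromosome 21, 41501128 to 41501339) and 410.0 bp inside HPGD, a prostaglandin-degrading enzyme gene, were also lost. ZBTB34 (859 bp), RNF146 (735 bp) and CORO2A (733 bp) held the widest lost sites with a gene within 100 kb.

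Basal markers gained 4 of 23 wide sites with bicalutamide at 5 h (17.4%, 4.95 to 38.8; percentile 96.8), including 141 bp inside CD44, a site also called with DHT, but 31 of 82 over all peaks (43.9). Over all peaks blood markers gained 17 of 29 sites (99.7) and stromal markers 22 of 49 (97.7), while among wide peaks these were 1 of 9 (78.4) and 2 of 14 (92.0). At the low end over all peaks were cell cycle genes (6 of 48, 0.26), androgen-induced genes (77 of 232, 1.01) and luminal markers (23 of 97, 1.72). Among wide peaks cell cycle genes gained 1 of 30 sites (36.6) and luminal markers 3 of 49 (66.4), so the low standing of these 2 lists rests on the narrow peaks. Androgen-repressed genes gained 4 of 22 (percentile 93.6), at BCHE, DDC, MET and OPRK1, and none of these sites was called in another list. Over all peaks 51172 of 126296 bicalutamide peaks had no vehicle peak (40.5%, 40.2 to 40.8) and 43875 of 116357 vehicle peaks had no bicalutamide peak (37.71%, 37.43 to 37.99). Wide bicalutamide peaks were gained in 2373 of 41164 cases (5.76%, 5.54 to 5.99), against 14.1% for DHT, and in each of the 5 width classes the DHT share was higher.

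**Figure D3:**
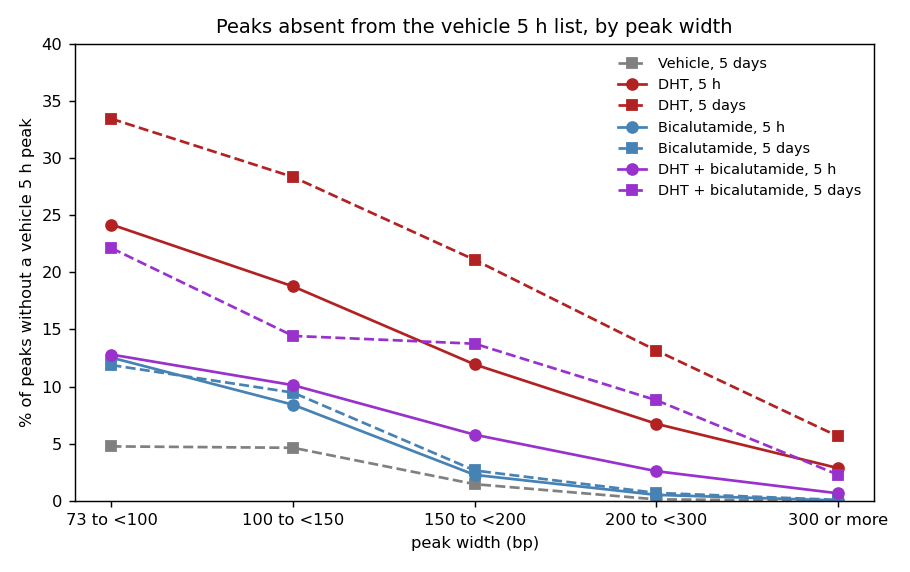
Percent of wide peaks without a vehicle 5 h peak (y axis) by peak width in bp (x axis, 5 classes) for the 7 other libraries. From the narrowest to the widest class the share went from 24.2% to 2.86% with DHT at 5 h, from 33.5% to 5.64% with DHT at 5 days and from 12.5% to 0.0262% with bicalutamide at 5 h.

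At 5 days, bicalutamide gained sites at the androgen-induced genes MAF (216 bp), ELL2 (205 bp) and KLK4 (202 bp), all of which were also called in vehicle at 5 h. The widest gained sites, at IDUA (646 bp), ACBD6 (641 bp), HELQ (576 bp), LIMS4 (544 bp) and RAD51B (542 bp), were called in vehicle at 5 h as well. Lost sites included SOCS2 (420 bp), a suppressor of cytokine signalling gene, RBM33 (393 bp), INIP (381 bp), UFC1 (360 bp) and the NR6A1 site that was also lost with DHT. Androgen-induced genes gained 45 of 85 wide sites (52.9%, 41.8 to 63.9; percentile 66.3). Over all peaks 48382 of 116008 were gained (41.7%, 41.4 to 42.0) and 20073 of 87924 vehicle peaks lost (22.8%, 22.6 to 23.1). Against vehicle of 5 h, 6.41% (6.14 to 6.68) of the wide bicalutamide peaks of 5 days were gained.

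Sites gained with both DHT and bicalutamide against the shared vehicle library were counted at 5 h. Of 6649 regions with a wide DHT-gained peak, 320 (4.81%) also had a wide bicalutamide-gained peak, against 1.66% for independent lists and 29.7% for simulated unchanged lists set against that vehicle list. At 5 days the value was 32.1% of 34772 DHT-gained regions, against 14.4% and 35.8%. Only wide peaks of every list entered these values, so a region with no more than a narrow vehicle call at 5 days counted as gained. Over all peaks it was 52.6% at 5 h, against 20.4% and 57.8%, and 33.6% at 5 days, against 18.0% and 48.3%. The value for independent lists was taken over all merged regions. Those with a vehicle peak were included, although they can be gained in neither list. It is therefore too low, and an excess over it may come from the shared vehicle library. The simulated calls were drawn by how many of the other lists held a region, whether or not the vehicle list of that time held it. Simulated gained sites can thus be of another kind than the observed ones. Neither value decides whether both agents gained the same sites.

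The combination of DHT with bicalutamide was compared with DHT alone to see which DHT sites were still called with the antagonist present. At 5 h the KLK3 site of 391 bp, the TRPM8 site of 260 bp and the STEAP4 site of 203 bp were not called with both agents, while the gained sites of FKBP5 (218 bp), ELL2 (216 bp) and PMEPA1 (245 bp) were. At 5 days the KLK3, TRPM8 and STEAP4 sites of the DHT 5 h list were called with both agents. The combination lists differ in shortest peak (20 bp at 5 h, 66 bp at 5 days) and in the number of wide peaks (27683 and 45300). A site called only in the later list therefore does not show a change with time. Sites inside TMPRSS2 (431 bp, chromosome 21, 41500924 to 41501355) and ABCC4 (311 bp), a transporter gene, which were also called in vehicle at 5 h, were lost at 5 h. The widest lost sites with a gene within 100 kb lay inside NINL (711 bp), ZNF483 (694 bp) and ABL2 (610.0 bp) and beside LRRFIP2 (627 bp), and the widest gained ones at YWHAH (570.0 bp), SIPA1L3 (495 bp), MAN1A2 (435 bp), REEP3 (422 bp) and CELF5 (378 bp).

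Androgen-induced genes lost 54 of 144 wide DHT sites at 5 h (37.5%, 29.6 to 46.0), against 34.8% over all genes, at the 78.9 percentile, and gained 5 of 82. Cell cycle genes lost 4 of 31 (percentile 0.5), and 17 of 51 over all peaks (13.3). Neuroendocrine markers lost 10 of 19 wide sites (95.9) but 19 of 52 over all peaks (26.5). Luminal markers gained 6 of 32 wide sites (96.7), including 145 bp at FOXA1, a pioneer factor gene, but 19 of 69 over all peaks (69.6). Of all DHT peaks at 5 h, 55594 of 141353 (39.3%, 39.1 to 39.6) had no peak in the combination, and 20662 of 106846 combination peaks (19.3%, 19.1 to 19.6) had no DHT peak. Among wide peaks these were 17397 of 48323 (36.0%, 35.6 to 36.4) and 2481 of 27683 (8.96%, 8.63 to 9.30).

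**Figure D4:**
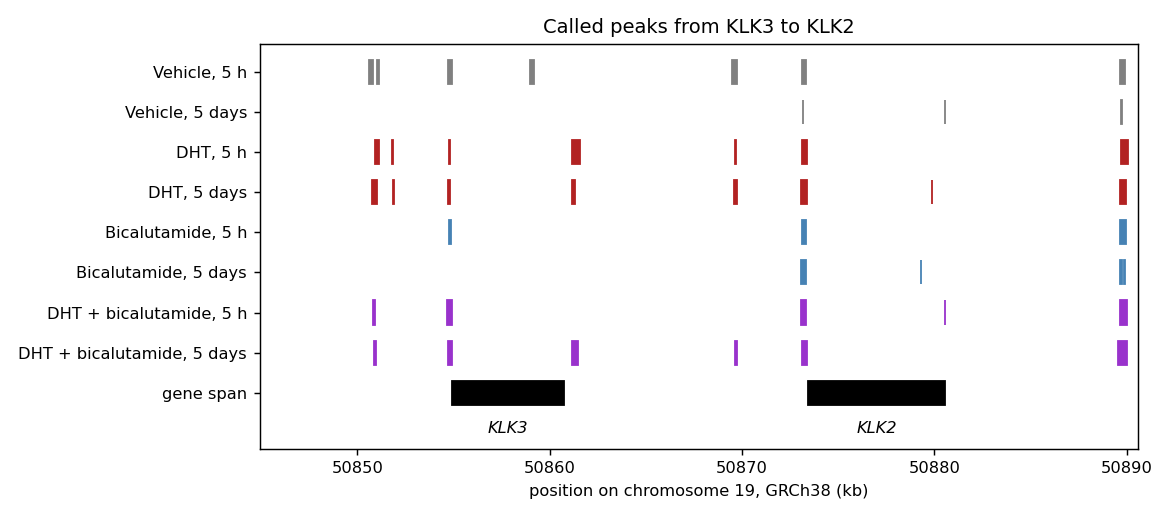
Peaks of the 8 lists drawn to scale (boxes, 1 row per library) over 45.7 kb around KLK3 and KLK2 on chromosome 19 (x axis, GRCh38 position in kb), with the gene spans in black. The site just beyond KLK3 (50861159 to 50861550 with DHT at 5 h) is called in both DHT lists and with both agents at 5 days, and not in the vehicle or bicalutamide lists.

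At 5 days the combination lacked DHT sites of 456 bp near ADAM7, 322 bp assigned to ACSL3 and 237 bp near SGK1, a kinase gene. The DDC site of 291 bp was lost as well. The widest lost sites were those of STXBP2 (599 bp), PPIC (534 bp), RSRP1 (494 bp), PPP3CA (488 bp) and ITGB3BP (484 bp). Gained sites at androgen-induced genes included 446 bp at CENPN. This list lost 47 of 129 wide sites (36.4%, 28.1 to 45.4; percentile 70.2), against 32.9% over all genes, and gained 18 of 120. Over all peaks it lost 180 of 305 sites (percentile 49.99), while fewer sites than in most random lists were lost by immediate early genes (36 of 85, 0.63), housekeeping genes (23 of 58, 0.815), luminal markers (46 of 97, 1.35), lipid synthesis genes (47 of 97, 3.84) and cell cycle genes (21 of 57, 4.55). Over all peaks 84275 of 139178 DHT peaks (60.6%, 60.3 to 60.8) had no combination peak, and 11687 of 66136 combination peaks (17.7%, 17.4 to 18.0) had no DHT peak. The combination list of 5 days holds no peak under 66 bp, and among wide DHT peaks the lost share was 34.1% (33.7 to 34.6).

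Of the 31 wide sites gained with DHT at 5 h at androgen-induced genes, 19 were called with DHT at 5 days, 8 with both agents at 5 h (25.8%, 11.9 to 44.6), 10 with both agents at 5 days, 4 with bicalutamide at 5 h and 1 with bicalutamide at 5 days. Over all genes and intergenic sites, 30.4% (29.4 to 31.6) of the 6822 wide gained DHT peaks were called in the combination at 5 h, against 58.7% for shared peaks of the same widths, and 15.7% (14.8 to 16.6) with bicalutamide alone, against 77.7%. In the DHT list of 5 days, which has no antagonist, it was 57.4%, against 74.6%, so gained peaks were found less often than shared ones there too. The draws matched width and not location, and 6.92% of the gained peaks lay within 1 kb of a gene end, against 22.0% of shared ones of the same widths. Whether location accounts for the gaps was not tested. The share in the combination went from 16.9% of those under 100 bp to 69.1% of those of at least 300 bp (165 peaks), and for shared peaks from 43.6% to 94.6%. With bicalutamide alone it stayed between 13.2% and 17.6%, while that of shared peaks went from 68.1% to 96.5%. Gained peaks of 5 days, defined against vehicle of 5 days, were called in the combination of 5 days in 51.6% of cases, against 84.3% at matched widths, with bicalutamide in 39.2%, against 88.1%, with DHT alone at 5 h in 64.8%, against 94.6%, and in vehicle at 5 h in 64.4%, against 96.8%. Over all peaks, narrow ones included, the shares were 53.0% (52.7 to 53.4) for the combination and 52.2% (51.8 to 52.6) for bicalutamide at 5 h, and 30.0% (29.7 to 30.3) and 31.8% (31.5 to 32.2) at 5 days.

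**Figure D5:**
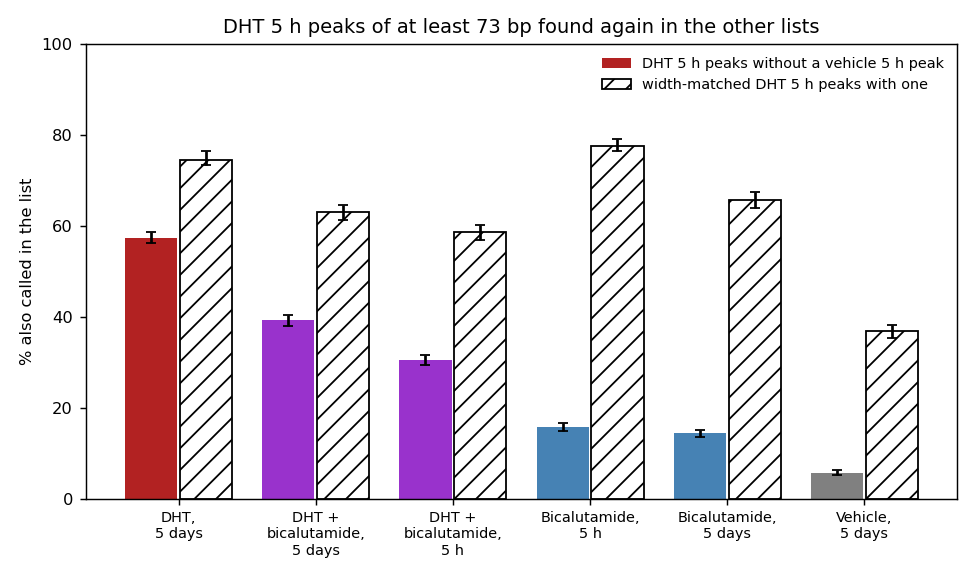
Percent (y axis) of the 6822 wide DHT 5 h peaks without a vehicle 5 h peak that were also called in each of 6 other lists (x axis; plain bars, exact 95% intervals of counting error), beside DHT 5 h peaks shared with vehicle and drawn at the same widths (hatched bars, mean of 1000 draws, error bars from the lowest to the highest draw). The gained peaks were found in 57.4% of cases with DHT at 5 days, in 39.2% and 30.4% with both agents at 5 days and 5 h, and in 15.7% and 14.3% with bicalutamide at 5 h and 5 days.

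Time was compared within each agent. Of the DHT peaks of 5 days, 29.0% (28.8 to 29.3) had no DHT peak at 5 h, and among wide ones 23.2%. DDC, SGK1 and STEAP4 each had a site called with DHT at 5 days and in no other list (291, 237 and 170.0 bp wide). The SLC45A3 site of 172 bp, inside this solute carrier gene, was called with DHT at 5 h and in no other list. The share was 26.5% (26.3 to 26.8) for bicalutamide and 31.0% (30.6 to 31.4) for both agents. For vehicle it was 49.8% (49.5 to 50.1) over all peaks and 3.04% among wide peaks, and the vehicle 5 h list holds no peak under 73 bp.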

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

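All tests in this part were chosen after the results they bear on had been seen, and none of the differences between times given here was tested.

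The sign of several differences from vehicle turned between the times. DHT minus vehicle in the number of wide peaks was -68034 at 5 h and 32969 at 5 days, and bicalutamide minus vehicle was -75193 and 17513. Sites gained minus lost at the androgen-induced genes (KLK3, TMPRSS2, FKBP5 and the others) numbered -55 at 5 h and 88 at 5 days for wide DHT peaks, and -106 and 40 for wide bicalutamide peaks. Over all bicalutamide peaks the same balance was -32 at 5 h and 69 at 5 days, whereas for DHT it kept its sign over all peaks (42 and 160) and with equal numbers (12 and 22). Lost sites in the wide-peak balances are wide vehicle peaks, so these balances follow the number of wide vehicle peaks.

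A change of the DHT and bicalutamide libraries between the times is argued against as the source of the turn, because their numbers of wide peaks differed by at most 1.28-fold between 5 h and 5 days, whereas vehicle differed by 8.01-fold. A technical candidate explanation is that the vehicle lists were called with different settings, since their shortest peaks were 73 and 20 bp. The other list with a long shortest peak (66 bp, both agents at 5 days) held 0.954 times as many wide peaks as DHT at 5 days. Against both agents at 5 h, where the shortest peak was 20 bp, it held more wide peaks (45300 against 27683). These comparisons differ in direction and do not decide whether a long shortest peak comes with more wide peaks. With 1 library per group the calling, the depth and a true effect of time in vehicle cannot be told apart.

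Peaks under 40 bp made up most of 6 lists. If placed like the wider peaks, they would lie at gene ends about as often. Their highest enrichment over shifted positions in any of the 6 lists was 3.07-fold, against at least 11.1-fold for wide peaks of the same lists. Wide peaks can also lie mostly away from gene ends, as did those gained with DHT at 5 h (6.92% within 1 kb). A low share at gene ends therefore does not decide whether the peaks under 40 bp are accessible sites. The hypothesis that they are positions called whatever the agent may hold, since 65.6% of them on average were found again (centres within 250 bp) between a DHT list and a list of another agent, and 64.9% between both DHT lists. For wide peaks, matched by overlap, these were 59.7% and 64.3%, so finding them again is not particular to peaks under 40 bp. Whether the positions mark alignment artefacts or weak open chromatin stays open, and no biological explanation was tested.

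At 5 h, wide DHT peaks lacked a vehicle peak more often than wide bicalutamide peaks did, by 2.45-fold, and by 2.63-fold when bicalutamide was weighted to the DHT widths, which argues against a different mix of peak widths as the cause. The number of DHT and bicalutamide peaks called is argued against as well, since against the whole vehicle list the ratio was 2.13 over the 41164 widest peaks of each and 9.49 over the 14534 widest. With the vehicle list also shortened to 14534 peaks the shares were 43.8% and 42.4%, against 5.09% and 0.537% with the whole list, so most of the unmatched peaks arise from the shortening itself and this setting decides nothing. Androgen action is a hypothesis that the androgen-induced list favours. Sites gained at its genes, such as KLK3, FKBP5 and ELL2, lay at the 99.0 percentile of random lists with DHT and at the 9.2 percentile with bicalutamide. Over all peaks, however, the DHT percentile was 33.2. Among wide DHT sites androgen-repressed genes (22.2%) and basal markers (26.1%) gained shares no smaller than the 21.5% of this list, at lower percentiles (88.8 and 83.5). Library quality and depth, which can differ between single libraries, stay open.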

How the results depend on the processing

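The reciprocal overlap and the 20 kb gene distance were planned, and the other settings (centres within 250 bp, wide peaks, equal numbers, other vehicle) were chosen after the data had been seen. Settings based on the authors' score (a stricter threshold, equal-length lists and the upper part of each list by score) and all motif settings had also been planned and were not run, because the lists hold no score and no genome sequence was used here. No analysis paired by replicate number was run, because each group holds 1 library. A fit of agent and time together over the 8 libraries, with time as a block, was not run either. Values are given for 5 h and then 5 days, and the cause of each shift was not tested except where the setting's construction shows it. A percent counts as unmoved when it stays within the counting interval of the value in the report. Of 78 alternative percents 74 moved by more. The 18 alternative percentiles of gene lists all lay outside an interval that covers only the drawing of the random lists. The depth that sets how many peaks are called is unknown.

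With an overlap of at least 50% of both peaks, the values were: DHT 77.6% and 59.2%, bicalutamide 77.3% and 50.8% without a vehicle peak, combination 34.7% and 61.9% without a DHT peak, DHT-gained peaks called in the combination 50.8% and 22.0%, with bicalutamide 52.1% and 21.4%, 5 day peaks without a 5 h peak 92.0% (vehicle), 43.8% (DHT), 40.7% (bicalutamide) and 73.1% (combination). Narrow peaks inside wide ones lose their match by construction, as against the vehicle 5 h list, and the order of the combination and bicalutamide in the share of DHT-gained peaks turned at both times.

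With centres within 250 bp the values were: DHT 45.4% and 49.4%, bicalutamide 39.6% and 39.5% without a vehicle peak, combination 16.7% and 15.5% without a DHT peak, DHT-gained peaks called in the combination 55.3% and 31.6%, with bicalutamide 54.5% and 35.5%, 5 day peaks without a 5 h peak 49.6% (vehicle), 26.0% (DHT), 23.1% (bicalutamide) and 29.0% (combination).

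With wide peaks of the first list against whole other lists they were: DHT 14.1% and 62.6%, bicalutamide 5.76% and 47.5% without a vehicle peak, combination 8.96% and 13.7% without a DHT peak, DHT-gained peaks called in the combination 30.4% and 51.6%, with bicalutamide 15.7% and 39.2%, 5 day peaks without a 5 h peak 3.04% (vehicle), 23.2% (DHT), 16.4% (bicalutamide) and 27.8% (combination). With wide peaks in every list they were: DHT 14.1% and 75.5%, bicalutamide 5.76% and 64.6% without a vehicle peak, combination 16.7% and 37.8% without a DHT peak, DHT-gained peaks called in the combination 15.2% and 49.2%, with bicalutamide 5.26% and 31.6%, 5 day peaks without a 5 h peak 3.04% (vehicle), 35.1% (DHT), 28.1% (bicalutamide) and 54.1% (combination). DHT had a higher share without a vehicle peak than bicalutamide under these settings, whereas at 5 h the intervals overlapped with the 50% overlap (77.4 to 77.8 against 77.1 to 77.5) and with equal numbers (42.9 to 44.6 against 41.6 to 43.2).

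With the 14534 widest peaks of every list the values were: DHT 43.8% and 56.0%, bicalutamide 42.4% and 46.6% without a vehicle peak, combination 40.2% and 41.2% without a DHT peak, DHT-gained peaks called in the combination 41.5% and 42.1%, with bicalutamide 35.4% and 27.8%, 5 day peaks without a 5 h peak 49.9% (vehicle), 42.4% (DHT), 40.9% (bicalutamide) and 40.1% (combination). Because both lists are shortened, gained and lost shares become alike by construction.

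With the vehicle library of the other time the values were: DHT 49.3% and 48.7%, bicalutamide 45.5% and 43.6% without a vehicle peak, DHT-gained peaks called in the combination 32.1% and 13.3%, with bicalutamide 43.3% and 46.9%. The order of the combination and bicalutamide in the share of DHT-gained peaks turned at 5 h here, and at 5 days it turned with wide peaks (both settings) and equal numbers.

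The percentile of sites gained minus lost at androgen-induced genes among random lists was 50.5 and 98.7 for DHT, 1.52 and 59.3 for bicalutamide and 15.3 and 52.9 for the combination against DHT over all peaks. With wide first-list peaks it was 99.6 and 81.9 for DHT, 47.1 and 63.6 for bicalutamide, 16.4 and 42.3 for the combination against DHT, with equal numbers 97.0 and 99.7 for DHT, 37.6 and 84.6 for bicalutamide, 29.8 and 42.7 for the combination against DHT, and with genes within 20 kb 60.8 and 91.9 for DHT, 2.44 and 34.1 for bicalutamide, 7.36 and 40.5 for the combination against DHT. DHT stood above 95 at 5 h with wide peaks and equal numbers, and at 5 days over all peaks and with equal numbers.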

Other observations

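The sets of sites in this part, and the tests on them, were chosen after the data had been seen. Wide DHT 5 h peaks that were called at both times with DHT and in no vehicle or bicalutamide list numbered 2850 of 48323 (5.90%, 5.69 to 6.11). The same rule gave 0.282% (0.233 to 0.338) of the 41164 wide peaks of bicalutamide at 5 h and 486 of 116357 for vehicle (0.418%, 0.381 to 0.456). These shares were not adjusted for list length, and bicalutamide and vehicle peaks had to be absent from the DHT lists, which were the longest. Androgen-induced genes held 16 of the DHT sites, at 12 of 30 genes, which lay at the 99.1 percentile of random gene lists with a median of 8. By the rule these 16 are part of the 31 wide sites gained at this list with DHT at 5 h, so this percentile is not separate support. FKBP5 held 3 of the 16 (154, 218 and 145 bp wide), SGK1 and TRPM8 held 2 each, and KLK3, ACSL3, PMEPA1, ELL2, STEAP4, STEAP2, ADAM7 and NDRG1 were among those that held 1 each. Androgen-repressed genes held 4, ACKR3, BCHE and OPRK1 among them (percentile 88.4). Luminal markers held 2 (KRT8 and CDH1, percentile 34.0), basal markers 3 (CD44, TP63 and DST, 85.1), neuroendocrine markers 1 (POU3F2) and stromal markers 1 (PDPN). Cell cycle, immediate early, lipid synthesis, housekeeping and blood genes held none, with random medians of 2, 2, 3, 2 and 0 sites.

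These 2850 sites lay within 1 kb of a gene end in 3.44% of cases, against 24.6% of the wide DHT 5 h list, without matching on width. For the bicalutamide sites of the same rule it was 15.5%, against 27.5% of their list, and for the vehicle sites 19.8%, against 14.6%. With both agents, 1108 of the 2850 DHT sites were called at 5 h (38.9%, 37.1 to 40.7) and 1748 at 5 days (61.3%, 59.5 to 63.1), 872 at both times and 866 at neither. The combination list held 27683 wide peaks at 5 h and 45300 at 5 days, and these shares were not adjusted for that. The FKBP5 sites of 154 and 218 bp and the sites of ELL2, PMEPA1, ACKR3, OPRK1, TP63 and PDPN were called with both agents at both times, while those of KRT8, ACSL3, SGK1, ADAM7, NDRG1 and DST were called with both agents at neither. The single listed site called in both bicalutamide lists and in no vehicle or DHT list lay inside ONECUT2, a neuroendocrine transcription factor gene (chromosome 18, 57445945 to 57446041), and the single one called in both vehicle lists and in no DHT or bicalutamide list lay near MET (chromosome 7, 116810426 to 116810631).

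Merged regions called in exactly 2 of the 6 single-agent lists were counted for the 15 pairs of lists. Both DHT lists shared 6040 such regions, and the highest of the 14 other pairs, vehicle and bicalutamide at 5 h, shared 4743. With a wide peak in both lists the numbers were 2028 and 1727, and with a wide peak in either list 4031 and 4743, where the DHT pair ranked 3 of 15. The DHT lists were also the longest (141353 and 139178 peaks), and no adjustment for list length was made. The counts therefore do not show that such sharing is particular to DHT.

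A stretch at lower coordinates than KLK3, between 50850590 and 50851104 on chromosome 19, was singled out after its calls were seen. It held a peak in vehicle at 5 h and in the 4 lists that contain DHT (133 to 279 bp for the widest peak of each of these), and none in either bicalutamide list or in vehicle at 5 days. Basal markers had 5 of 21 wide bicalutamide sites of 5 days without a vehicle 5 h peak (23.8%, 8.22 to 47.2; percentile 99.5), a list picked here from 11 lists and 7 libraries after the values were seen.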
